A study of Mus musculus with 6 samples.

How the data were processed

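Messenger RNA was measured in 6 male mouse mesonephroi at E14.5, 3 ARKO (Osr2-Cre with floxed Ar) and 3 control (floxed Ar without Cre), grouped by the genotype in the labels. Per the labels' protocols, RNA was taken from frozen tissue with a PicoPure kit, poly-A RNA was pulled down with oligo-dT beads, and fragments were copied from random hexamers. A kit that keeps strand is not named there. The submitters' processing notes name STAR, Partek, DESeq2 and the build mm10, with no versions. The annotation and the counting rule are not given in the sources used here, so overlapping, antisense and near-identical genes are reported as uncertain.

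The analysed files were 2 versions of 1 comparison by the authors, ARKO against control, made with DESeq2 per the file headers. The authors deposited p-values and a step-up FDR, the ratio of the group means, its log2, a signed fold change with 95% limits, and group means as a signal of normalized reads (least-squares means of the model). They also deposited the total of normalized reads over the 6 libraries and the highest value of any 1 library, without saying which library it was. How the authors normalized the reads is not stated in the headers. The table lists 21772 genes, each with a total of at least 9.29, and 17551 carry an FDR. The 4221 without one are those with the lowest totals, up to 45.67, and stayed out of counts of calls. Both versions hold the same ratios and means (largest relative difference 9.1e-15).

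Values per library were not analysed here. The design written before the data were examined called for limma on log2 values per library, and that test was replaced by the authors' DESeq2 comparison. Alternatives that need values per library were not run either. No depth per library, SD or permutation test is therefore given; the totals came to 14023524 normalized reads per library on average, and group means summed to 13774890 in ARKO and 14271860 in control. The precision of each ratio is that of the authors' 95% limits. No column of another series was present.

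The standard error of each log2 ratio was computed from the 95% limits, and its Wald z from the ratio and this error. The p-value recomputed from z differed from the authors' p-value by at most 0.0052 in log10, and Benjamini-Hochberg adjustment of the authors' p-values gave back the deposited FDR (largest difference 2.6e-14). A gene was called at a deposited FDR under 0.05. Among the listed genes 96.6% matched the name, position and strand of GENCODE M21 (GRCm38), after the stop coordinate was lowered by 1 base, and coordinates are given 1-based.

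In total 38 gene lists were fixed from textbook knowledge before the data were examined. Lists were tested with camera on the z values themselves and not on their ranks (cameraPR of limma 3.58.1 in R 4.3.3). The test was two-sided, over 16836 genes with a mean of at least 10 normalized reads over the 6 libraries. The preset correlation between genes was 0.01, and p was adjusted over the 36 lists with at least 5 tested members. An estimated correlation needs values per library, so a preset correlation of 0.05 was run in its place. In 20 simulated data sets, z was drawn for the same 16836 genes of ARKO against control. The test called 1.33% of 600 tests of unshifted lists. It called 17.5% of lists shifted by 0.5 SD, 60.0% of those shifted by 0.7 SD and 97.5% of those shifted by 1 SD, in 40 tests at each size. The shifted lists were drawn from the larger lists and all their members were shifted alike. These rates therefore do not cover small lists or lists in which only some members move. The simulated z were independent between genes, so these rates do not cover lists whose members vary together. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

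Named genes followed a rule written before the data were examined. It takes Ar and Osr2, the 12 largest rises and 12 largest falls among called genes with a mean of at least 50, the genes with the 5 smallest FDRs, and in each list up to 4 called members, or the 2 with the smallest p where none was called. Its demand that all 3 ARKO values lie on one side of the 3 control values was not applied, and unnamed gene models were counted but not named among rises and falls. Shh, Gli1, Pnp, Duxbl1, Duxbl3, Tbx3 and Kcnq1 in the results, and genes outside the rule in the closing section, were chosen after their values were seen. For lists past neither the test nor a gene's threshold, the 1 member with the smallest p is given.

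Alternatives for counts, named genes and lists were no filter, a mean of at least 50, an FDR under 0.1 and an absolute log2 ratio above 1. Those added later were protein-coding genes only, a mean of at least 10, ratios recentred on the median of genes with a mean of at least 50 (-0.03), a quadratic trend over transcript length and GC content taken out, the highest library of each gene or list member set aside (taken to lie in the group with the higher mean), a correlation of 0.05, and ranks. Length and GC content were those of the longest GENCODE M21 transcript, known for 97.6% of genes, and the trend, fitted on 11958 protein-coding genes, took 6.1% of the variance.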

Results

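Poly-A RNA of male mouse mesonephroi at E14.5 was sequenced to ask what the androgen receptor of the mesenchyme contributes to gene expression around the Wolffian duct, the embryonic tube from which the epididymis and vas deferens form. The series held 3 mesonephroi that carried the Osr2-Cre driver and a floxed androgen receptor gene (ARKO) and 3 that carried the floxed gene without Cre (control). No group carried Cre without the floxed gene, so an effect of the driver cannot be told apart from loss of the receptor. The dissected tissue left out the region of the mesonephric tubules, per the labels. The values analysed were those of the authors' deposited table, which compares the groups gene by gene and gives group means of normalized reads, ratios with 95% limits and p-values. Values per library were not analysed here, so the spread behind each ratio is given by the authors' 95% limits. The total over the 6 libraries was 84141141 normalized reads, or 14023524 per library on average. The labels do not say whether the mesonephroi of a group came from separate litters, so p-values measure the spread between these libraries.

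The floxed gene itself was lower in ARKO mesonephroi. Ar, the androgen receptor (chromosome X, 98148769 to 98323215, mm10), had a mean of 157.3 normalized reads in ARKO and 555.6 in control in the authors' deposited table, 3.53-fold lower with 95% limits of 2.56 to 4.87 and a DESeq2 FDR of 6.9e-11. The labels do not say which exon was floxed, and the source of the Ar reads that remained in ARKO was not tested. Osr2, whose regulatory sequence drives Cre, was 1.22-fold lower with limits of 0.999 to 1.49 in the authors' deposited table and did not pass (FDR = 0.46).

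More genes were lower than higher in ARKO. Of 17551 genes with an FDR in the authors' deposited table, 75 passed 0.05 by DESeq2, 53 of them lower and 22 higher in ARKO. Of the 53 genes that fell, 50 were protein-coding and 3 were processed pseudogenes. Of the 22 that rose, 7 were protein-coding, 7 were of the class TEC (single-exon models still awaiting experimental support), 5 were lincRNAs and 3 were antisense RNAs. Coding and other genes were split unequally between the directions (Fisher's exact test, two-sided, p = 4.3e-08, across genes, which are not independent replicates). Recentring the ratios on their median changed the counts to 33 higher and 43 lower, and taking out the trend over transcript length and GC content changed them to 32 higher and 40 lower.

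The smallest FDRs belonged to falls. Acta2, the smooth muscle alpha-actin (chromosome 19, 34241090 to 34255590), was 2.24-fold lower (limits 1.86 to 2.71, FDR = 8.4e-13) in the authors' deposited table. Cldn8, a claudin of tight junctions in duct epithelia (chromosome 16, 88560828 to 88563183), was 3.08-fold lower in the authors' deposited table (limits 2.36 to 4.02, FDR = 9.4e-13). Dcdc2a, a doublecortin-domain protein (chromosome 13, 25056004 to 25210706), was 2.58-fold lower there, in the authors' deposited table, with limits of 1.97 to 3.38 and an FDR of 1.9e-08. The gene model Gm49342 (chromosome 14, 50944517 to 50963136) had means of 2.26 in ARKO and 59.7 in control in the authors' deposited table (FDR = 6.1e-08). It overlaps Pnp and Pnp2 on the same strand and its reads cannot be assigned with certainty, and Pnp itself had means of 608.9 and 672.1 in the authors' deposited table (FDR = 0.78).

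**Figure D1:**
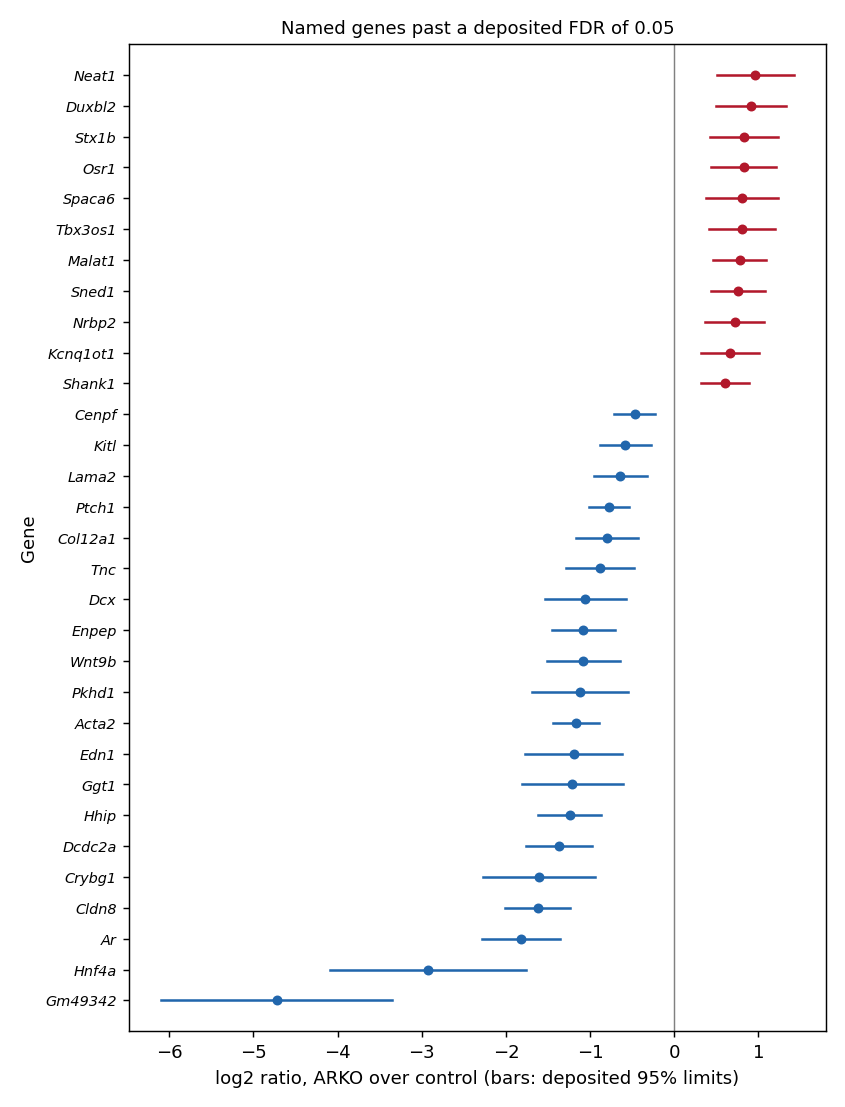
Log2 ratio of ARKO over control (x axis) for each named gene past a deposited FDR of 0.05 (y axis), from the authors' deposited table; points are ratios, bars are the authors' 95% limits, blue is lower and red is higher in ARKO. The 11 named rises lie between 0.61 and 0.97, and Ar lies at -1.82.

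Hhip and Ptch1 fell among the hedgehog pathway genes. Hhip, a hedgehog-binding target gene, was 2.37-fold lower (limits 1.83 to 3.07, FDR = 2.4e-07) and Ptch1, the hedgehog receptor and target gene, 1.71-fold lower (limits 1.45 to 2.02, FDR = 5.9e-07) in the authors' deposited table. Shh, the ligand, was 1.96-fold lower in the authors' deposited table and did not pass (FDR = 0.088). Gli1, a further target gene, was 1.02-fold higher in the authors' deposited table with limits of 0.803 to 1.31 (FDR = 0.96). Of 13 members tested, 2 fell and 11 did not pass, 11 had ratios below 1, and 4 fell when p was adjusted over the list alone. The list ranked lower than other genes (limma camera, adjusted p = 4e-06, and adjusted p = 0.00028 with a preset correlation of 0.05). Its median log2 ratio was -0.13 and its mean -0.33, so that a few members carried the shift. Camera on ranks gave the list an adjusted p of 0.012.

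Genes of the dividing cell ranked lower than other genes. Cenpf, a kinetochore protein, was the single member past the threshold over all genes, 1.38-fold lower in the authors' deposited table (limits 1.17 to 1.64, FDR = 0.046). Of 37 proliferation genes tested 34 had ratios below 1, the median log2 ratio was -0.33, and 20 fell when p was adjusted over the list alone. The list was lower by limma camera (adjusted p = 1.6e-15, and adjusted p = 1.6e-07 with a correlation of 0.05). The Cenpf call in the authors' deposited table was lost when p was adjusted over all listed genes (adjusted p = 0.057), after recentring (adjusted p = 0.079) and after the length and GC correction (adjusted p = 0.26), which moved its log2 ratio from -0.47 to -0.34.

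The extracellular matrix list ranked lower as well. Tnc, the matrix glycoprotein tenascin C, was 1.84-fold lower (limits 1.39 to 2.43, FDR = 0.012), Col12a1, a fibril-associated collagen, 1.74-fold lower (limits 1.35 to 2.25, FDR = 0.013) and Lama2, a laminin chain of basement membranes, 1.56-fold lower (limits 1.25 to 1.94, FDR = 0.025) in the authors' deposited table. Of 51 members tested these 3 fell and 48 did not pass, with 42 below 1, a median log2 ratio of -0.25 and 12 falls when adjusted over the list alone (camera adjusted p = 3e-10, and adjusted p = 0.00019 with a correlation of 0.05). After the length and GC correction of the authors' deposited ratios, Col12a1 had an adjusted p of 0.051, with a log2 ratio of -0.80 before and -0.70 after, and Lama2 of 0.10, with -0.64 before and -0.54 after. Matrix remodelling enzymes had a median of -0.14 over 32 members, with none past the threshold and 1 fall adjusted over the list alone (camera adjusted p = 0.0043, and adjusted p = 0.069 with a correlation of 0.05). Timp3, a metalloproteinase inhibitor, was 1.30-fold lower and Serpine2, a protease inhibitor, 1.26-fold lower in the authors' deposited table (FDR = 0.12 and 0.21).

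Smooth muscle genes had a median log2 ratio of -0.13, with 17 of 21 below 1, Acta2 past the threshold and 2 falls adjusted over the list alone (camera adjusted p = 0.002, and adjusted p = 0.029 with a correlation of 0.05). Kidney and nephron markers had a median of -0.22 over 11 members, with 1 fall over all genes and 1 over the list alone (camera adjusted p = 0.0043, and adjusted p = 0.029 with a correlation of 0.05). Among genes with a mean of at least 50 normalized reads the kidney list did not pass (adjusted p = 0.078). Its called member, Hnf4a, a transcription factor of proximal tubule and liver, was 7.61-fold lower (limits 3.39 to 17.1, FDR = 0.00097) from means of 7.72 in ARKO and 58.7 in control in the authors' deposited table. With the highest library of this gene taken out of the control mean, its log2 ratio from the authors' deposited table moved from -2.93 to -2.25.

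Duct epithelium was represented by Wnt9b, a Wnt ligand made by the Wolffian duct, which was 2.11-fold lower in the authors' deposited table (limits 1.56 to 2.86, FDR = 0.0013). Of 25 Wolffian duct epithelium markers 1 fell and 24 did not pass, 3 fell when adjusted over the list alone, and the median log2 ratio was -0.12 (camera adjusted p = 0.015, and adjusted p = 0.11 with a correlation of 0.05). Of 42 Wnt pathway genes Wnt9b was the single fall by either adjustment and the median was -0.14. Camera gave the Wnt genes an adjusted p of 0.048, and an adjusted p of 0.23 with a correlation of 0.05. Camera on ranks gave an adjusted p of 0.088 for the duct markers and 0.056 for the Wnt genes. The remaining large falls among named genes in the authors' deposited table were Crybg1 (3.05-fold, FDR = 0.0021), Ggt1, a gamma-glutamyl transferase (2.31-fold, FDR = 0.025), Edn1, the vasoconstrictor endothelin 1 (2.29-fold, FDR = 0.020), Pkhd1, fibrocystin of primary cilia (2.18-fold, FDR = 0.032), Enpep, an aminopeptidase that cleaves angiotensin (2.11-fold, FDR = 2e-05), and Dcx, doublecortin (2.08-fold, FDR = 0.011). The Pkhd1 call was lost in the authors' deposited ratios after the length and GC correction (adjusted p = 0.069), with a log2 ratio of -1.12 before and -1.01 after.

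Paracrine growth factors held 2 falls among 36 members, Edn1 and Kitl, the ligand of the Kit receptor, which was 1.49-fold lower in the authors' deposited table (limits 1.21 to 1.84, FDR = 0.043). Over the list alone 2 members fell and 2 rose, and the list did not pass (median -0.11, camera adjusted p = 0.17). The Kitl call in the authors' deposited table was lost when p was adjusted over all listed genes (adjusted p = 0.054), after recentring (adjusted p = 0.072) and after the length and GC correction (adjusted p = 0.14), which moved its log2 ratio from -0.58 to -0.48. Insulin-like growth factor genes had a median of -0.09 over 17 members, none past the threshold and 2 falls over the list alone. Their camera adjusted p was 0.015, with 0.083 at a correlation of 0.05 and 0.065 on ranks. Pappa2 and Igfbp2, which regulate insulin-like growth factors, were 1.75-fold and 1.34-fold lower in the authors' deposited table (FDR = 0.058 and 0.11).

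Hox genes, the positional transcription factors of the body axis, ranked higher than other genes. Of 35 tested 31 had ratios above 1 and the median log2 ratio was 0.30 (camera adjusted p = 5.6e-07, and adjusted p = 0.0011 with a correlation of 0.05). None passed over all genes, and 1 rose over the list alone. With the highest library of each member taken out of the mean of its higher group, the Hox median in the authors' deposited table was 0.11 with 26 above 1. The same step moved the median of 3535 coding genes with log2 ratios between 0.1 and 0.5 from 0.21 to 0.10. Hoxb5 was 1.80-fold higher (limits 1.29 to 2.52, FDR = 0.090) and Hoxd10 1.43-fold higher (limits 1.12 to 1.84, FDR = 0.22) in the authors' deposited table. Both overlap other gene models, Hoxb5 on the opposite and Hoxd10 on the same strand, and strand use in counting is not given in the sources used here. Mitochondrially encoded genes had a median of 0.22 over 13 members with 12 above 1 and none past either threshold (camera adjusted p = 0.048, and adjusted p = 0.13 with a correlation of 0.05). After the length and GC correction their adjusted p was 0.82, and with each highest library taken out their median was 0.02. Both mt-Nd1 and mt-Nd6, subunits of respiratory complex I, were 1.21-fold higher in the authors' deposited table (FDR = 0.61 and 0.62).

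The named rises were small and leaned more on a single library than the falls. With the highest library of each gene taken out of the mean of its higher group, 8 of 11 named rises and 1 of 20 named falls moved by more than their standard error, and Spaca6 moved from 0.81 to 0.41 on the log2 scale of the authors' deposited table. The highest library lay at a median of 1.38 times the group mean for called rises and 1.12 times for called falls in the authors' deposited table. Osr1, a transcription factor of intermediate mesoderm, was 1.77-fold higher in the authors' deposited table (limits 1.36 to 2.31, FDR = 0.013). Malat1 and Neat1, RNAs retained in the nucleus, were 1.71-fold (limits 1.38 to 2.13, FDR = 0.0015) and 1.95-fold higher (limits 1.42 to 2.68, FDR = 0.015) in the authors' deposited table. Sned1, a matrix protein, was 1.69-fold higher and Nrbp2 1.65-fold higher in the authors' deposited table (FDR = 0.0029 and 0.023). Stx1b and Shank1, proteins of synapses, were 1.78-fold and 1.52-fold higher in the authors' deposited table (FDR = 0.021 and 0.015). The antisense RNAs Tbx3os1 (1.74-fold, FDR = 0.023) and Kcnq1ot1 (1.58-fold, FDR = 0.042) were higher in the authors' deposited table, and overlap Tbx3 and Kcnq1 on the opposite strand, so reads of each pair cannot be told apart. Duxbl2, 1.88-fold higher in the authors' deposited table (FDR = 0.012), is uncertain because near-identical copies, Duxbl1 and Duxbl3, are listed separately. Spaca6 was 1.75-fold higher in the authors' deposited table (FDR = 0.049). When p was adjusted over all listed genes of the authors' deposited table, Spaca6 (adjusted p = 0.060) and Kcnq1ot1 (adjusted p = 0.052) lost their calls. Shank1 lost its call after the length and GC correction (adjusted p = 0.053), which moved its log2 ratio from 0.61 to 0.53, and Spaca6 among protein-coding genes only (adjusted p = 0.052). The named rises numbered 11 because the other 11 rises were unnamed gene models.

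Alongside these rises, intronic and little-annotated transcripts were higher across the table. The 709 TEC genes had a median log2 ratio of 0.76 in the authors' deposited table, 55 sense intronic genes of 0.81, 393 antisense genes of 0.37 and 300 lincRNAs of 0.31, against -0.03 for 14004 protein-coding genes. Taking the highest library of each gene out of the ARKO mean lowered the joint TEC and sense intronic median from 0.76 to 0.39. The same step put coding genes of the same mean at -0.26. Processed pseudogenes had a median of -0.17 in the authors' deposited table over 889 genes. Across 12097 protein-coding genes with a mean of at least 50, the log2 ratio in the authors' deposited table fell with the length of the gene on the chromosome (Spearman's rho = -0.25 across genes, which are not independent replicates).

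**Figure D2:**
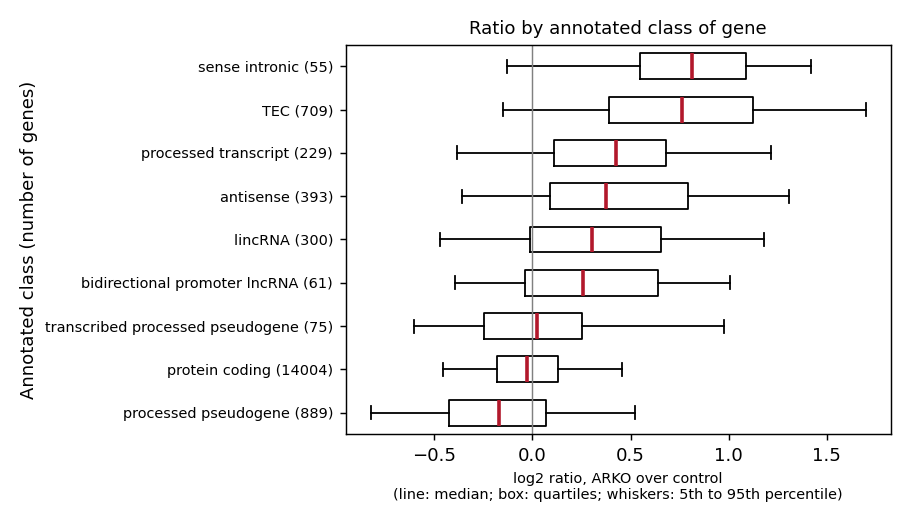
Log2 ratio of ARKO over control (x axis) by annotated class of gene (y axis, number of genes with a mean of at least 10 normalized reads), from the authors' deposited table; red lines are medians, boxes are quartiles and whiskers reach the 5th and 95th percentiles. TEC and sense intronic genes have medians of 0.76 and 0.81, and protein-coding genes of -0.03.

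Androgen-related and glucocorticoid lists were lower by camera with a correlation of 0.01 but not with 0.05, and Ar was their only called member. Steroid receptor and androgen metabolism genes, a list that contains the floxed gene, had a median of -0.08 over 13 members, with Ar as the 1 fall by either adjustment. Their camera adjusted p was 0.048, with 0.13 at a correlation of 0.05 and 0.37 on ranks. Setting aside each member's highest library turned their median to 0.043, with 7 members above 1 and 6 below. Androgen response genes defined in prostate had a median of -0.09 over 84 members with none past either threshold (camera adjusted p = 0.014, and adjusted p = 0.19 with a correlation of 0.05). Their members with the smallest p, Cdk6 and Rps6ka3, were 1.30-fold and 1.29-fold lower in the authors' deposited table (FDR = 0.22 and 0.29). Glucocorticoid feedback genes had a median of -0.29 over 15 members, none past either threshold (camera adjusted p = 0.014, and adjusted p = 0.069 with a correlation of 0.05). Klf15 was 2.51-fold and Errfi1 1.31-fold lower in the authors' deposited table (FDR = 0.21 and 0.33).

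Further lists were lower by camera with a preset correlation of 0.01 but not with 0.05. Axon guidance and ephrin genes had a median of -0.21 over 35 members (adjusted p = 0.0039, and adjusted p = 0.069 with a correlation of 0.05), with Plxna2 1.26-fold and Slit3 1.46-fold lower in the authors' deposited table (FDR = 0.34 and 0.32). Endothelial markers had a median of -0.27 over 17 members (adjusted p = 0.014, and adjusted p = 0.069 with a correlation of 0.05), with Mmrn2 1.56-fold and Pecam1 1.45-fold lower in the authors' deposited table (FDR = 0.23 and 0.30). Immediate early and heat shock genes had a median of -0.17 over 23 members (adjusted p = 0.042, and adjusted p = 0.15 with a correlation of 0.05), with Fos 4.17-fold lower (limits 1.33 to 13.1) and Egr1 1.58-fold lower in the authors' deposited table (FDR = 0.33 and 0.34). With its highest library taken out of the control mean, the log2 ratio of Fos from the authors' deposited table moved from -2.06 to -1.11. No member of these 3 lists passed over all genes or over the list alone.

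**Figure D3:**
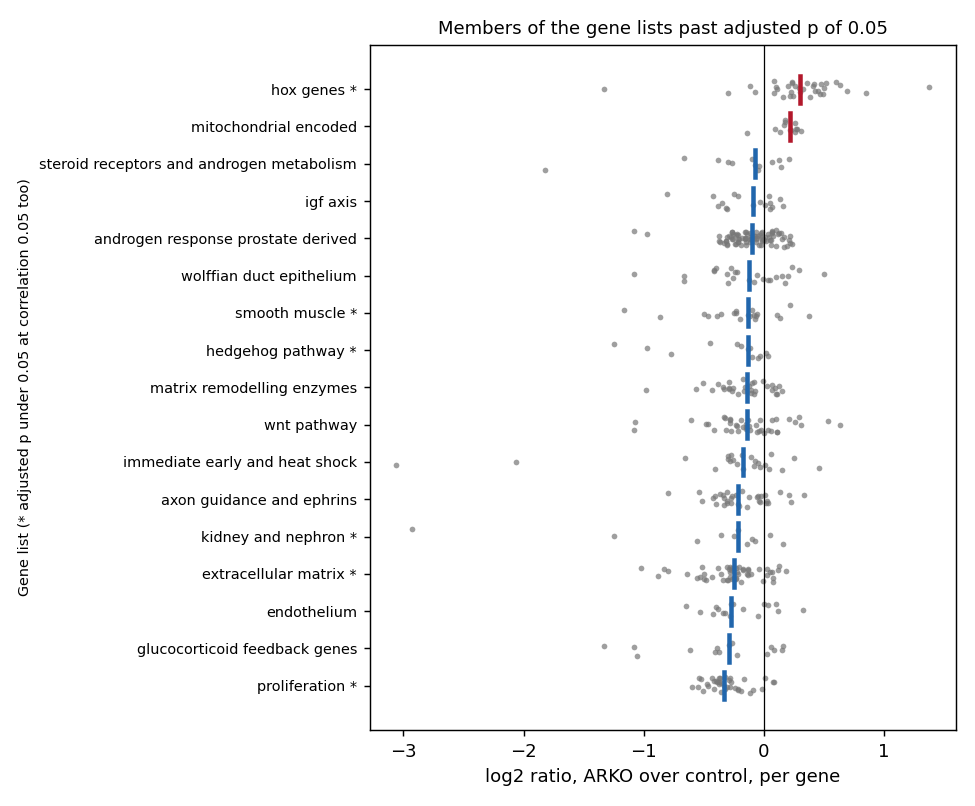
Log2 ratio of ARKO over control (x axis) of each tested member (grey points, from the authors' deposited table) of the 17 gene lists past an adjusted p of 0.05 (y axis); thick lines are medians, and an asterisk marks the 6 lists that also passed with a correlation of 0.05. The medians run from -0.33 for proliferation to 0.30 for Hox genes.

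The other 19 lists tested did not pass. Mesenchyme markers had a median of -0.04 over 25 members, with Osr1 the 1 rise by either adjustment (camera adjusted p = 0.81). Müllerian duct genes had a median of 0.00076 over 19 members (adjusted p = 0.78), with Msx2 the 1 rise over the list alone, 1.52-fold higher in the authors' deposited table (FDR = 0.17). Medians and adjusted p were -0.10 and 0.60 for the FGF pathway, -0.06 and 0.25 for BMP and TGF-beta, -0.04 and 0.81 for retinoic acid, -0.12 and 0.54 for Notch, and -0.10 and 0.60 for apoptosis and cell cycle arrest. Hypoxia and glycolysis genes had a median of 0.03 (adjusted p = 0.19), with 1 rise over the list alone, and interferon response genes a median of 0.07 with a mean of -0.06 (adjusted p = 0.76). Vegfa in the authors' deposited table was 1.53-fold higher (FDR = 0.11), Fgfr3 1.30-fold higher (FDR = 0.40), Tgfbr1 1.24-fold lower (FDR = 0.22), Rbp4 3.71-fold lower (FDR = 0.21), Hes1 1.23-fold higher (FDR = 0.47), Cdkn1a 1.37-fold lower (FDR = 0.22) and Rsad2 1.63-fold lower (FDR = 0.48).

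Markers of other cell types did not pass either. Medians and adjusted p were 0.11 and 0.53 for Leydig cells, -0.15 and 0.25 for Sertoli and gonadal support cells, -0.23 and 0.11 for pericytes, -0.04 and 0.42 for macrophages and leukocytes, and -0.37 and 0.25 for erythroid cells. They were 0.10 and 0.52 for neurons and glia, -0.15 and 0.30 for mesothelium, -0.07 and 0.60 for cartilage and bone, and 0.90 and 0.052 for skeletal muscle. Mesothelium and skeletal muscle each held 1 rise over the list alone, Rspo1 (1.45-fold, FDR = 0.17) and Tnnt1 (1.86-fold, FDR = 0.13) in the authors' deposited table. Gata4 in the authors' deposited table was 1.75-fold lower (FDR = 0.29), Ptprc 1.52-fold lower (FDR = 0.38), Cspg4 1.19-fold lower (FDR = 0.57), Tfrc 1.29-fold lower (FDR = 0.32), Hand2 1.23-fold higher (FDR = 0.35), Hapln1 1.27-fold lower (FDR = 0.44) and Ldlr 1.18-fold higher (FDR = 0.63). Germ cell and sex-linked genes had 2 and 4 tested members, under the minimum of 5, with medians of -0.46 and 0.02, and the authors' deposited table put Ddx4, a germ cell helicase, 2.31-fold lower (FDR = 0.45) and Eif2s3y, a Y-linked gene, 1.33-fold higher (FDR = 0.46).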

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

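The correlation of 0.05, ranks, recentring, coding genes only, the length and GC correction, the filter at a mean of 10 and the steps that set aside the highest library were chosen after the data were seen. No paired analysis was possible because the deposited comparison carries no values per library. For the same reason leaving out each library, other pseudocounts, TMM and quantile normalization, library weights, other variance models, edgeR and DESeq2 refits, camera with an estimated correlation and fry were not run, and other splits of the 6 libraries could not be counted. The androgen receptor log2 ratio kept its direction and call in the 5 alternatives with a test, between -1.82 and -1.71, and was -1.75 with its highest library set aside. The count of 75 genes stayed between 55 and 77 under the filters, coding genes only, recentring and the length and GC correction, and 62 of the 75 remained with no filter and 58 after the length and GC correction. It was 131 (52 higher) at an adjusted p under 0.1 and 32 (9 higher, 23 lower) with an absolute log2 ratio above 1, by the construction of those thresholds. Higher calls numbered 6 among coding genes only, where fewer genes are tested, and 14 where no library exceeded 1.5 times the mean of the higher group. Lists lower in ARKO numbered 15, but 5 with a correlation of 0.05 and 9 at a mean of at least 50. Lists higher in ARKO numbered 2, but 1 with a correlation of 0.05, 1 with no filter, 1 after recentring and 1 after the length and GC correction; the cause was not tested. Over 504 alternatives for the other named genes 13 lost a call, 1 gained one (Igfbp2 after the length and GC correction, adjusted p = 0.0099) and no called gene changed sign. With the highest library set aside 20 ratios moved by more than their standard error, and 3 genes that were not called changed sign: Actc1 from 1.20 to -1.0, Fdx1 from 0.09 to -0.03 and Uty from -0.07 to 0.02 (0.01 after the length and GC correction). Over 250 alternatives for lists 33 lost a call, 1 gained one (skeletal muscle among coding genes only, adjusted p = 0.030) and none reversed. With each member's highest library set aside, the median of the steroid receptor list reversed from -0.075 to 0.043, of the 17 lists past the threshold the only median to change sign; the cause was not tested. Genes with low totals had wide limits, as for Hnf4a, and differences there were detectable only when large.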

Other observations

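The tests of a single library, those on lists included, of one scaling factor and of duct and tubule genes were chosen after the values were seen, as were the genes named in this part. Bootstrap intervals here resampled genes, which are not independent replicates, so they do not measure the spread between libraries.

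Further falls lay outside the fixed lists and were picked by hand. Tmem72 in the authors' deposited table was 5.58-fold lower (FDR = 5.9e-07), Slc26a3, an anion exchanger, 7.18-fold lower (FDR = 0.013), Aldh1a7, an aldehyde dehydrogenase, 6.04-fold lower (FDR = 0.021), Tfcp2l1, a transcription factor of kidney collecting ducts, 1.87-fold lower (FDR = 0.00028), Cldn1, a tight junction claudin, 1.69-fold lower (FDR = 0.021) and Lamc2, a laminin chain of epithelial basement membranes, 1.55-fold lower (FDR = 0.020). With the highest library taken out of the control mean, the log2 ratios from the authors' deposited table moved from -2.84 to -1.95 for Slc26a3 and from -2.59 to -1.87 for Aldh1a7. Ccnd2, a cyclin, was 1.46-fold lower (FDR = 0.041) and Fbxo32, a ubiquitin ligase subunit, 1.72-fold lower (FDR = 3.1e-05) in the authors' deposited table.

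Plasma protein genes of the fetal liver and yolk sac were close to absent outside a single library each. In the table deposited by the authors, 1 library held 96.0% of Alb reads and 1 held 92.9% of Afp reads, with means of 114.3 and 133.4 in control against 4.40 and 6.97 in ARKO, and neither gene passed (FDR = 0.60 and 0.47). Apoa1, Gc and Serpina6 had 86.7%, 80.9% and 98.6% of their reads in 1 library, with higher means in control (FDR = 0.65, 0.33 and 0.60). Of 9 genes with over 80% of reads in 1 library, 6 had the higher mean in control and 3 in ARKO. Whether these genes share a library is not known.

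The higher ratios of TEC and sense intronic genes covered 91.5% of 764 genes. A single ARKO library was argued against as the whole cause. With the highest library taken out of the ARKO mean of every gene, their median went from 0.76 to 0.39. Coding genes of the same mean went from 0.04 to -0.26, a difference of 0.65 (bootstrap 95% interval over genes 0.60 to 0.72). The step also lowers genes whose highest library was a control library, so part of the 0.65 can come from the subtraction. A scaling factor was argued against too, since the difference with all libraries was 0.73 (0.66 to 0.79). Genomic DNA was predicted to raise TEC genes inside and outside genes alike, which assumes similar counts and lengths in both sets. The sets were not matched on either, so their gap cannot decide on DNA. TEC genes inside a coding gene on the same strand exceeded those outside by 0.44 (0.31 to 0.54 over genes), narrowly beyond the 0.3 set beforehand. That interval does not cover spread between libraries, so it does not show that other libraries would give the same difference. Unspliced or nuclear RNA of host genes is a candidate explanation for that difference. TEC genes outside coding genes still had a median of 0.44, and a contribution from DNA of any size stays open. Whether this reflects RNA quality, tissue handling or the knockout was not tested.

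The lower proliferation and matrix lists and the higher Hox list were set against transcript length and GC content. After that trend was taken out, the medians were -0.29 for proliferation (camera adjusted p = 1.8e-13), -0.21 for extracellular matrix (adjusted p = 8.1e-10) and 0.33 for Hox genes (adjusted p = 4e-06). These values argue against the trend over transcript length and GC content as the whole cause. The separate trend over the length of the gene on the chromosome was not taken out and stays open. With each member's highest library taken out of the mean of its higher group, the medians were -0.28, -0.15 and 0.11, and part of the Hox shift from a single ARKO library stays open. Differences in nuclear RNA between the groups, differences in stage between embryos and an effect of the knockout stay open and were not tested.

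Duct and tubule epithelial genes were weighed on 12 genes picked by hand from the 53 falls: Wnt9b, Cldn8, Tfcp2l1, Pkhd1, Cldn1, Lamc2, Hnf4a, Tmem72, Slc26a3, Ggt1, Enpep and Aldh1a7. These 12 were set against tissue in a single control library as the whole cause. Without each gene's highest library their median log2 ratio was -1.0 (bootstrap 95% interval over genes -1.91 to -0.89). That library lay at 1.05 to 1.92 times the control mean, where a single source would need 1.71 to 2.74 times, lower than needed for 12 of 12. The falls of these 12 were therefore not confined to a single control library each. Picking among calls favours falls shared by several libraries, so this outcome was largely set by the choice of genes. It does not decide against tissue in a single control library for other genes. Genes that were not called, such as Pdzk1 (2.29 times the control mean), are not covered. A lower share of duct epithelium was set against the Wolffian duct list. The list's median of -0.12 lay above the -0.99 of the 6 duct genes by 0.87, more than the list's SD of 0.35. Of the list's 25 members, 9 had ratios above 1 and 16 below. The gap cannot decide the question, because genes picked for falling exaggerate it. Some list members, such as Krt7 and Krt19, also stood in the mesothelium list. A loss of epithelium, tubule tissue in a single or several control libraries and a response of the epithelium to the loss of mesenchymal Ar stay open, the last untested.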
